A study of Arabidopsis thaliana with 3 samples.

How the data were processed

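The series measured transcript levels in whole seedlings of Arabidopsis thaliana carrying XVE_mTCP3, a construct in which estradiol switches on a form of the transcription factor gene TCP3. Per the labels, seedlings were grown on plates at 22 °C with 16 h of light a day, moved at day 10 into liquid medium, kept there for 36 h under continuous light with agitation, and then given 5 µM estradiol or the solvent DMSO for 16 h. Per the labels' protocols, labelled cRNA was made from 1 µg of total RNA, and each of the 3 Agilent arrays carried estradiol RNA in Cy5 and DMSO RNA in Cy3. The labels call the 3 arrays biological replicates. Each array is therefore 1 replicate of 1 direct comparison, and the pairing of both RNAs is contained in the ratio. No array carried the opposite dye orientation, so a dye effect particular to a gene cannot be told apart from the treatment. No estradiol-treated plants without the construct were analysed here, so an effect of estradiol itself is part of every ratio. All 3 arrays lay on 1 slide and were scanned in 1 run, per the file headers, so no slide or scan block could be fitted.

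The deposited scanner files were written by Agilent Feature Extraction 9.1.3.1, per the file headers. They give, for each of 39102 spots, the mean intensity of each channel, the median intensity of the local background, and a processed intensity that the scanner software had background-subtracted, detrended and dye-normalized, per the file headers. They also give a deposited log10 ratio of Cy5 over Cy3 processed intensity, set to 0 where both channels had surrogate values, and flags of other kinds for uneven, outlying, saturated and dim spots. The authors' series table holds the natural log of the ratio of processed intensities plus a constant of 0.178, found by setting each column against the scanner values of its array (slope 0.693 against the log2 ratio on every array). This constant is 0.256 on the log2 scale, and the reason for it is not given in the sources used here. The column medians of that table were 0.0955, 0.0997 and 0.109 for arrays 1, 2 and 3. Its direction was that of the scanner ratio, estradiol over DMSO. No column of that table lay outside the series.

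Ratios were recomputed from the mean and background intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on all spots, and log2 ratios were normalized by loess within each array, with control spots and spots with an outlier flag at weight 0. The 1417 control spots and the outlier spots (87 to 118 per array) were then left out, and spots of the same probe were averaged (23 probes had 10 spots each). A probe was kept when it was well above background on all 3 arrays in at least 1 channel and had values on at least 2 arrays. Of the 37478 probes, 26236 carry a locus name, 8812 are named for a chromosome interval and 2430 carry another name. Of the 25665 loci named, 25449 were found in the RefSeq gene table of assembly TAIR10.1, which was used for symbols and for gene order; otherwise the locus name of the array was kept. Locus names are those of the array design and can be old, and no coordinates are given because the sources used here name no build for the array. A gene with several kept probes was represented by the probe with the highest mean intensity. Among 434 such genes with values on all arrays, 5 had probes called in opposite directions (AT2G27775, AT3G12340, AT4G08240, ALDH3I1 and RD19).

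Signal over background sets the precision of each array. The median intensity of non-control spots was 83.2 to 88.4 in Cy3 against a background of 35.5 to 38, and 150 to 166 in Cy5 against 46 to 48. Between 59.5% and 59.9% of probes were well above background in Cy3 and between 63.9% and 64.1% in Cy5. No spot was saturated. The number of arrays limits the precision of every value. The observed log ratios of the spike-in controls had slopes of 0.929 to 0.939 against the added ones, per the file headers. Where a gene was not well above background on any array in 1 channel, only a bound is given. It sets the bright channel against, per array, the higher of the lowest signal among probes well above background and the gene's own signal, after loess and Aquantile scaling, and is open to dye bias.

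Each log2 ratio was tested against 0 with limma's moderated test (lmFit and eBayes), with Benjamini-Hochberg adjustment over 22743 features (19969 genes and 2774 probes without a locus name) and a threshold of 0.05 on the adjusted p. Every adjusted p of a gene comes from this test. The p-values rest on the spread over the 3 arrays, drawn toward a variance shared by all features. Of 5.79 total degrees of freedom 3.79 came from that shared variance, so a p-value does not reflect the gene's own SD alone. The fit was tested on simulated log2 ratios of 22645 features with 200 changed. With variances drawn from the fitted prior, 85.1% of the changes of 0.5 and 97% of those of 1 were recovered, 4.48% of those of 0.25 were recovered, and 3 of 127 calls were false. With variances taken from the fitted genes, 50.7% of the changes of 0.25 were recovered, and 21 of 188 calls were false. Only 200 features were changed there, whereas 44.7% of the genes were called in the data. The adjustment depends on the share changed, so these recoveries and false calls do not carry over to the real fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 33 lists. At an estimated correlation camera rests on the residual degrees of freedom of only 3 arrays and had little power. A high adjusted p from that form thus leaves open whether a list changed.

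The design, the 31 hand-written lists, the rules for 2 further lists (ribosomal protein and histone genes, by their descriptions), the rule for named genes and the alternative settings below were fixed before the data were examined. The rule names the 8 CIN-class TCP genes, reported TCP3 or TCP4 targets and CUC1, CUC2 and CUC3 whatever their value, the 12 largest rises and 12 largest falls among genes past the threshold with the same sign on all 3 arrays, and up to 4 members of each list past the threshold with the largest absolute log2 ratio. These settings were no background correction, plain subtraction, an offset of 10, the scanner software's log ratio, the authors' series table, median centring in place of loess, scaling between arrays, other filters on dim probes, the mean of a gene's probes, an intensity trend with a robust fit, and leaving out each replicate. The series table centred on its medians, a correction for probe base composition, and a test against a change of 1.5-fold were chosen after seeing the data. A look at TCP binding sites in upstream sequence was not run, since no genome sequence was used here.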

Results

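Transcript levels were compared between XVE_mTCP3 seedlings given 5 µM estradiol and seedlings given DMSO for 16 h, on 3 arrays that each carried both RNAs. Between 59.5% and 64.1% of the probes were well above background per array and channel. Over genes, the log2 ratios of arrays 1 and 2 correlated at r = 0.90, those of arrays 1 and 3 at 0.753 and those of arrays 2 and 3 at 0.77; genes are not independent replicates. Values below are log2 ratios of estradiol over DMSO, as mean ± SD over the 3 arrays (n = 3) unless an array is named.

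The comparison asks which transcripts change when the TCP3 transgene is switched on. TCP3 (AT1G53230), a gene for a CIN-class TCP transcription factor, had a log2 ratio of 3.70 ± 0.15 (12.9-fold, adjusted p = 2.23e-05), with 3.87, 3.62 and 3.59 on arrays 1, 2 and 3. The native gene and the transgene were not told apart, since the probe was not placed on either transcript here. Of the other CIN-class genes, TCP4 fell by 0.73 ± 0.08, TCP10 by 0.26 ± 0.09 and TCP24 by 0.15 ± 0.07, while TCP17 rose by 0.26 ± 0.17. TCP2 (-0.05 ± 0.18), TCP5 (-0.09 ± 0.05) and TCP13 (-0.03 ± 0.06) were not called. The list of 8 CIN-class genes thus had 2 members higher and 3 lower, also when adjusted over the list alone. Its median was -0.07, its mean 0.33 through TCP3, and camera did not call it (adjusted p = 0.614). The TCP17 call ended without replicate 1 (0.19) or replicate 3 (0.23), that of TCP10 without replicate 2 (-0.22), and that of TCP24 without replicate 1, 2 or 3 (-0.17, -0.11 and -0.16), while TCP2 was called lower without replicate 3 (-0.16). With median centring, which puts the median gene at 0.46, TCP4 was at -0.12 and not called, and TCP2, TCP5, TCP10, TCP13 and TCP24 had ratios above 0. Of the 12 measured TCP genes of other classes, 1 rose and 6 fell, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.101). The rise was that of TCP6, which was not well above background with DMSO on any array, so its sign is not settled. TCP23 fell by 0.71 ± 0.11 and TCP21 by 0.57 ± 0.06.

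**Figure D1:**
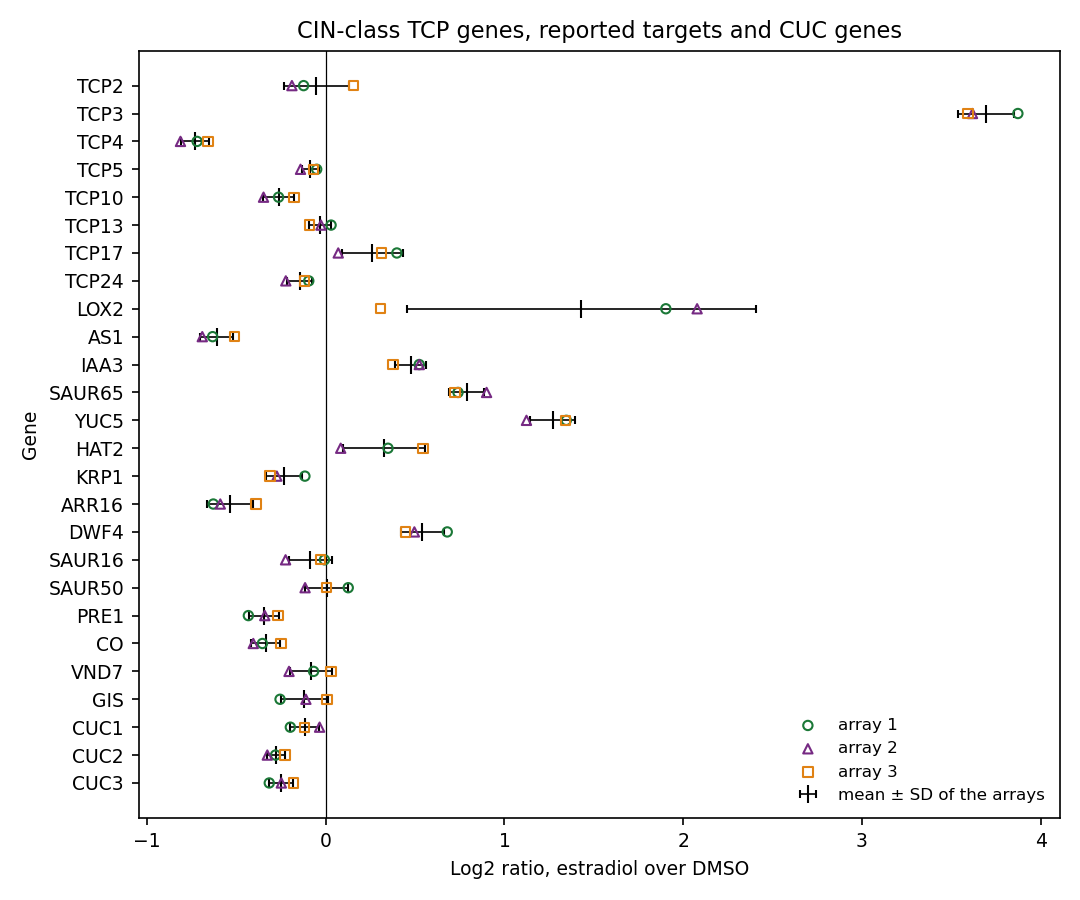
Log2 ratio of estradiol over DMSO (x axis) for the CIN-class TCP genes, the reported TCP3 or TCP4 targets and the CUC genes. Open symbols are the 3 arrays, and the bar is their mean ± SD. TCP3 lies between 3.59 and 3.87, and LOX2 lies at 0.31 on array 3 against 1.90 and 2.08 on the others.

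Reported targets of TCP3 or its close relative TCP4 went both ways. YUC5, an auxin synthesis gene, rose by 1.27 ± 0.13 (2.41-fold, adjusted p = 0.000222). SAUR65 rose by 0.79 ± 0.10, DWF4 of brassinosteroid synthesis by 0.54 ± 0.12, and the auxin response repressor gene IAA3 by 0.47 ± 0.08. LOX2, a lipoxygenase gene of jasmonate synthesis, rose by 1.43 ± 0.98 with 1.90, 2.08 and 0.31 on arrays 1, 2 and 3. HAT2 rose by 0.33 ± 0.23. AS1, a MYB gene of leaf development, fell by 0.61 ± 0.09, the cytokinin response gene ARR16 by 0.54 ± 0.13, PRE1 by 0.35 ± 0.08, CO by 0.34 ± 0.08 and KRP1 by 0.23 ± 0.10. SAUR16 (-0.09 ± 0.12), SAUR50 (0.00 ± 0.12), VND7 (-0.08 ± 0.12) and GIS (-0.12 ± 0.13) were not called. Of 15 measured targets, 6 were higher and 5 lower, also when adjusted over the list alone. The median was -0.08, the mean 0.17, and camera did not call the list (adjusted p = 0.903). Published work on these targets may rest partly on the same plants, so their direction is not independent evidence. The LOX2 call ended without replicate 1 (1.19) and also without replicate 2. The KRP1 call ended without replicate 2 (-0.21) and the HAT2 call without replicate 1 (0.31) or replicate 3 (0.22), while GIS was called lower without replicate 3 (-0.18).

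Over all genes, 4547 were higher and 4375 lower with estradiol, which is 44.7% of the 19969 tested. Most changes were small at the offset used here. The median absolute log2 ratio of the called genes was 0.256, and 86.8% of them lay under 0.5. At least 2-fold changes were seen in 70 higher and 137 lower genes, against 463 and 223 with the authors' series table, 653 and 56 with median centring, and 110 and 141 without replicate 3. They were also larger with the scanner software's log ratio (228 and 345), plain background subtraction (163 and 275), an offset of 10 (110 and 202) and the centred series table (219 and 353). The offset of the background correction is added to both channels and shrinks the ratios of dim spots. Part of the small size of the changes thus comes from this setting, and how large a part was not tested. Sizes given here for dim genes may therefore be too small. The sign was the same on all 3 arrays for 8881 of the 8922 called genes. Of these calls 51% were rises; with the authors' series table, whose median gene lies at 0.26, the counts were 12038 higher and 1327 lower, and with median centring, whose median gene lies at 0.46, they were 15709 and 1710. Directions here are relative to spots of like intensity, at which loess centres the ratios. Without replicate 1 the counts were 2537 and 2729, and without replicate 2 they were 2480 and 2531. Tested against a change of 1.5-fold, 54 genes were higher and 140 lower.

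**Figure D2:**
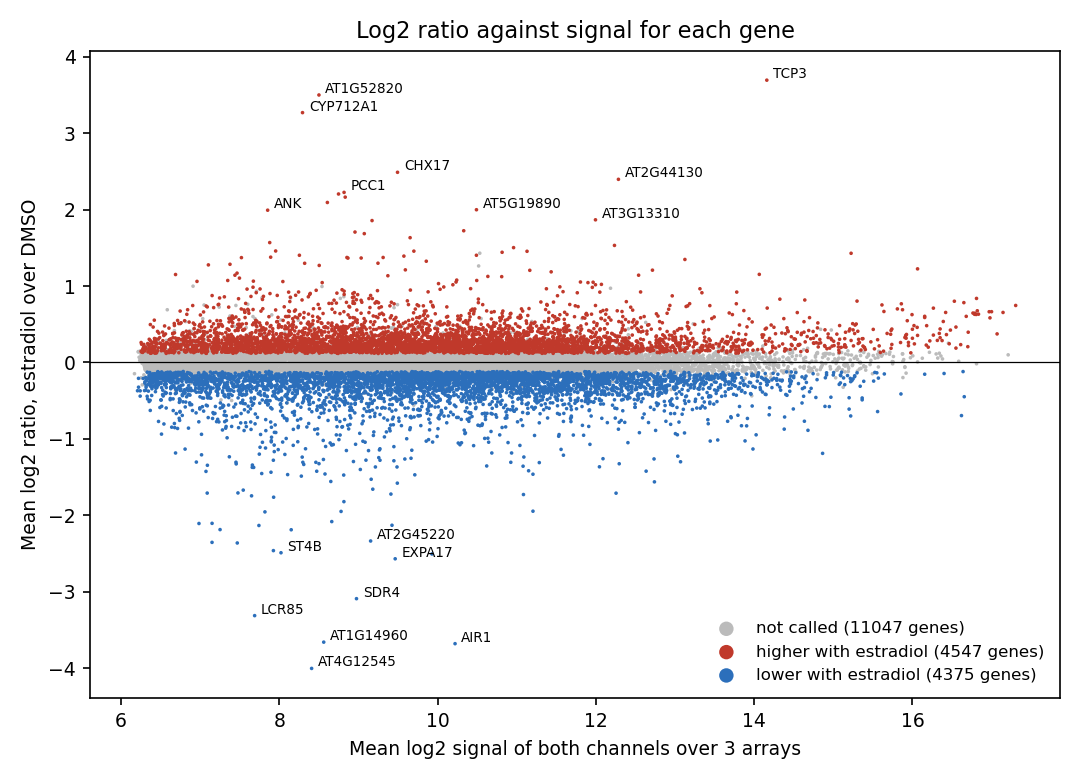
Mean log2 ratio of estradiol over DMSO (y axis) against the mean log2 signal of both channels (x axis) for 19969 genes, 1 point per gene. Red points are the 4547 genes called higher, blue points the 4375 called lower and grey points the 11047 not called; names mark genes among the 12 largest rises and 12 largest falls, where there was room.

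After TCP3, the largest rise was that of AT1G52820, a 2-oxoglutarate-dependent dioxygenase gene, at 11.3-fold (SD of the log2 ratio 0.32, adjusted p = 0.000102), with 3.80, 3.54 and 3.16 on arrays 1, 2 and 3; it was well above background with DMSO on 2 of the 3 arrays. CYP712A1, a cytochrome P450 gene, rose by 3.27 ± 0.15 and CHX17, a cation/proton exchanger gene, by 2.49 ± 0.08. The log2 signal with DMSO was only 6.75 for AT1G52820 and 6.66 for CYP712A1. The offset shrinks ratios of such dim genes, so these rises may be larger than given. TCP3, with a log2 signal of 12.31 with DMSO, hardly moved (3.70, against 3.71 with an offset of 10). The order of the rises may thus differ with the offset. The kelch-repeat F-box gene AT2G44130 rose by 2.40 ± 0.30. PCC1 rose by 2.23 ± 1.03, with 3.26 on array 3 and lower values on arrays 1 and 2. Of the basic helix-loop-helix genes of the iron deficiency response, bHLH38 rose by 2.21 ± 0.65, bHLH39 by 2.16 ± 0.75 and bHLH100 by 2.09 ± 0.88. The peroxidase gene AT5G19890 rose by 2.00 ± 0.55, the ankyrin repeat gene ANK by 1.99 ± 0.50 and the DnaJ-domain gene AT3G13310 by 1.87 ± 0.21. With an intensity trend and a robust fit the calls of PCC1, bHLH39 and bHLH100 ended.

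Among the 12 largest falls, AT4G12545 and its neighbour AIR1 (AT4G12550), both of the lipid transfer protein family, fell by 4.01 ± 0.09 (16.1-fold, adjusted p = 8.59e-06) and 3.68 ± 0.20. AT1G14960, related to major latex proteins, fell by 3.66 ± 0.17, LCR85 fell by 3.31 ± 0.21 and the short-chain dehydrogenase gene SDR4 fell by 3.09 ± 0.21. LCR85 was well above background with estradiol on 2 of the 3 arrays. The log2 signal with estradiol was 6.41 for AT4G12545 and 6.03 for LCR85. Since the offset shrinks ratios of such dim genes, these falls may be larger than given. The order of the 12 largest falls may also differ with the offset. EXPA17, an expansin gene, fell by 2.57 ± 0.08, the peroxiredoxin gene AT1G65970 by 2.51 ± 0.21, the sulfotransferase gene ST4B by 2.49 ± 0.12 and the pectinesterase gene AT2G45220 by 2.34 ± 0.10. CYP71A16 of the marneral pathway fell by 2.46 ± 0.26, and AT5G47980, which lies beside the thalianol pathway gene CYP705A5, fell by 2.36 ± 0.23. CYP705A5 was not well above background with estradiol on any array and was at least 4.92-fold lower there (adjusted p = 0.000198).

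Organ boundary and meristem genes fell as a list. Of 18 measured, 9 fell and 0 rose, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.00304, adjusted p = 0.796 with an estimated correlation). The class 1 KNOX homeobox genes KNAT2 and KNAT6 fell by 0.67 ± 0.01 and 0.57 ± 0.03, and LOB by 0.51 ± 0.01. CUC2 fell by 0.28 ± 0.05 and CUC3 by 0.25 ± 0.07, while CUC1 was at -0.12 ± 0.08 (adjusted p = 0.0899). The list of GRF and GIF growth regulators, with 14 genes measured, also holds ANT and ARGOS. In it 1 gene, ARGOS, rose and 7 fell, also when adjusted over the list alone. Camera did not call the list (adjusted p = 0.0556), though it did without replicate 3 (median -0.17, adjusted p = 0.0077 at the preset correlation). With an estimated correlation over all 3 arrays the camera adjusted p was 0.796. ANT fell by 0.71 ± 0.24, GRF5 by 0.56 ± 0.24 and GRF6 by 0.48 ± 0.05. Among 13 leaf polarity genes 2 rose and 3 fell (1 and 2 adjusted over the list alone, median 0.03, mean -0.04, camera adjusted p = 0.793), AS1 furthest. Of 37 cell cycle genes 2 rose and 4 fell, also when adjusted over the list alone (median -0.02, camera adjusted p = 0.514). CYCD3;2 fell by 0.53 ± 0.11 and CYCA2;2 rose by 0.30 ± 0.04. Without replicate 3 the cell cycle list was called lower, with a median of -0.08 (adjusted p = 0.0137 at the preset correlation; adjusted p = 0.939 with an estimated correlation over all 3 arrays). Of 9 CDK inhibitors 2 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.11, camera adjusted p = 0.793), with KRP2 at 0.27 ± 0.08. Relative to the median gene, the medians of the leaf polarity, cell cycle, CDK inhibitor and trichome lists had the other sign with median centring.

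Among hormone lists, cytokinin response and turnover genes fell. Of 18 measured, 11 fell and 1 rose, also when adjusted over the list alone (median -0.23, camera adjusted p = 0.000671, adjusted p = 0.796 with an estimated correlation). The response regulator gene ARR6 fell by 0.92 ± 0.10, the cytokinin synthesis gene IPT5 by 0.87 ± 0.19 and ARR4 by 0.43 ± 0.05. SAUR genes, a family of small auxin-responsive genes, rose as a list. Of 19 measured, 14 rose and 1 fell, also when adjusted over the list alone (median 0.28, camera adjusted p = 0.00276, adjusted p = 0.796 with an estimated correlation). The estimated correlation between members was 0.394, above the preset 0.01, so the 14 rises are not independent of each other. SAUR26 rose by 0.53 ± 0.10 and SAUR21 by 0.51 ± 0.20, while SAUR15 fell by 0.69 ± 0.19. Abscisic acid, cold and drought response genes also rose as a list, with 9 of 17 higher and 0 lower, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.00546, adjusted p = 0.796 with an estimated correlation). P5CS1 of proline synthesis rose by 0.73 ± 0.21, NCED3 of abscisic acid synthesis by 0.72 ± 0.11 and RAB18 by 0.65 ± 0.16. The SAUR and abscisic acid calls also ended with the authors' series table and with median centring.

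Other hormone lists held members in both directions and were not called. Of 32 AUX/IAA and GH3 genes 14 rose and 9 fell, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.367). GH3.17 and GH3.2, for enzymes that conjugate auxin, fell by 1.05 ± 0.06 and 0.78 ± 0.14, while IAA2 rose by 0.53 ± 0.06. Of 15 auxin synthesis and transport genes 3 rose and 4 fell, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.793). TAR2 of auxin synthesis fell by 1.25 ± 0.24 and TAA1 by 0.38 ± 0.06, against the rise of YUC5; the median of this list had the other sign, relative to the median gene, with the authors' series table. Of 10 brassinosteroid genes 4 rose and 2 fell, also when adjusted over the list alone (median 0.06, camera adjusted p = 0.614). BR6OX1 rose by 0.50 ± 0.02 and CPD by 0.49 ± 0.20, and BAS1, for an enzyme that inactivates brassinosteroids, fell by 0.46 ± 0.19. Of 13 gibberellin genes 3 rose and 3 fell, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.692), with GAI at 0.34 ± 0.07 and GA2OX6 at -0.39 ± 0.13.

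Jasmonate genes differed between arrays. All 15 measured jasmonate response genes and all 14 biosynthesis genes had a lower ratio on array 3 than the mean of arrays 1 and 2. The response list had medians of 0.50, 0.37 and -0.64 on arrays 1, 2 and 3, and VSP2, a vegetative storage protein gene chosen after its values were seen, had 2.42, 1.35 and -1.25. Over all arrays 2 response genes rose and 1 fell (1 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.692). JAZ6 had -0.47 ± 0.30 and JAZ3 0.34 ± 0.20. The JAZ6 call ended without replicate 2 (-0.48) and its ratio was -0.31 without replicate 3, and the JAZ3 call ended without replicate 1 (0.29) or replicate 2 (0.27). Of the biosynthesis genes 3 rose and 1 fell (3 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.634). AOS, the allene oxide synthase gene, rose by 1.15 ± 0.54 and JAR1, for the enzyme that conjugates jasmonate to isoleucine, by 0.40 ± 0.03. Without replicate 3 both lists were called higher, with medians of 0.42 for jasmonate response (adjusted p = 0.00214) and 0.25 for jasmonate biosynthesis (adjusted p = 0.00497). These are calls at the preset correlation, and over all 3 arrays both lists had an adjusted p = 0.939 with an estimated correlation. Xenobiotic response genes also had a lower ratio on array 3 in 16 of 17 members, as did 16 of 21 glucosinolate genes (median difference -0.14), 13 of 20 flavonoid and anthocyanin genes (-0.20) and 12 of 17 abscisic acid, cold and drought response genes (-0.06), whereas 2 of 37 cell cycle genes (median difference 0.18), 2 of 15 auxin synthesis and transport genes and 3 of 19 SAUR genes did. Of the 17 xenobiotic response genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone, median -0.27, camera adjusted p = 0.0872). The transporter gene DTX1 fell by 1.31 ± 0.04, OPR1 by 1.02 ± 0.43 and UGT74E2 by 0.95 ± 0.51. The xenobiotic response list was called lower without replicate 1 or without replicate 2 (medians -0.40 and -0.38, adjusted p = 0.0416 and 0.0204 at the preset correlation; adjusted p = 0.901 with an estimated correlation over all 3 arrays).

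**Figure D3:**
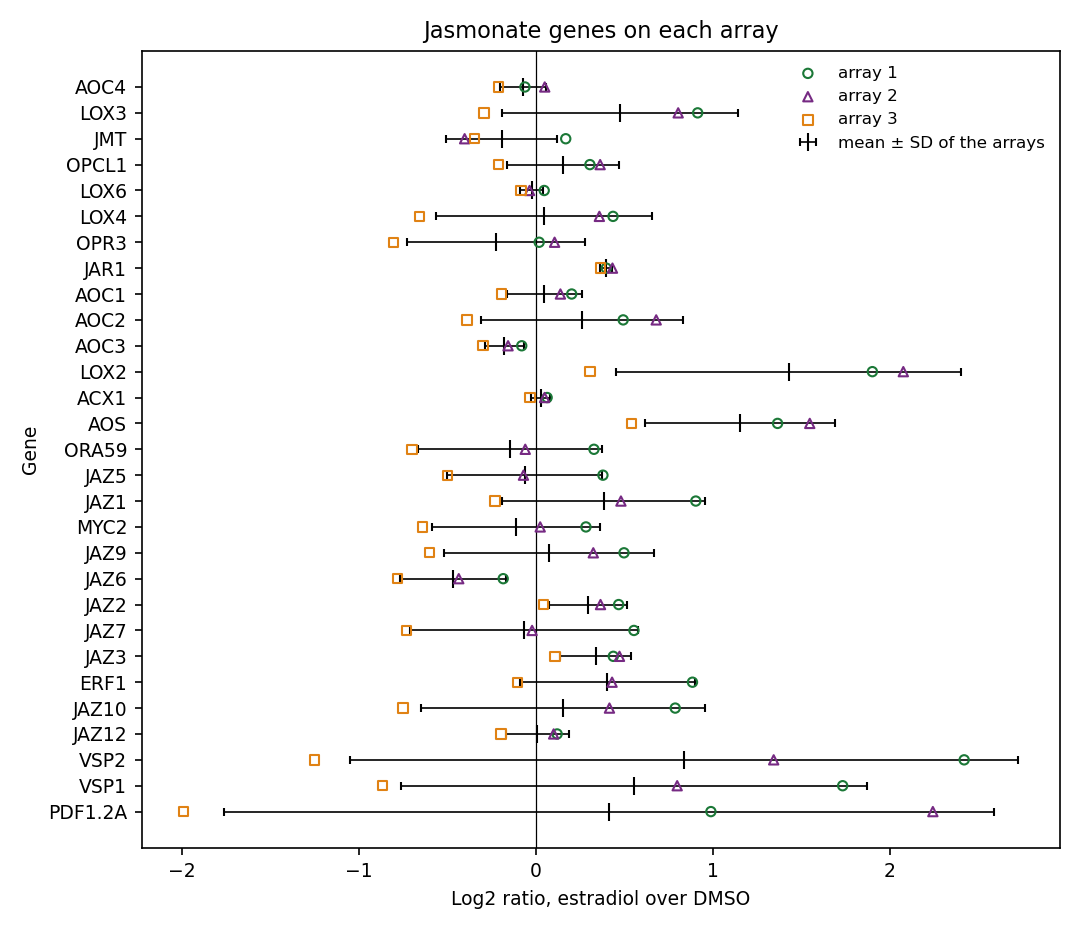
Log2 ratio of estradiol over DMSO (x axis) for each measured gene of the jasmonate biosynthesis and jasmonate response lists. Open symbols are the 3 arrays, and the bar is their mean ± SD. For VSP2 the arrays lie at 2.42, 1.35 and -1.25, and JAR1 lies at 0.40 ± 0.03.

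Genes of salicylic acid and defence rose as a list, with 7 of 18 higher and 0 lower, also when adjusted over the list alone (median 0.24, camera adjusted p = 0.00348, adjusted p = 0.796 with an estimated correlation). The pathogenesis-related genes PR5 and PR2 rose by 1.72 ± 0.12 and 1.37 ± 0.55, PBS3 by 0.96 ± 0.25 and the regulator gene WRKY70 by 0.79 ± 0.07. Senescence genes had 11 of 19 higher and 4 lower (12 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 0.0142, adjusted p = 0.796 with an estimated correlation). ORE1, a senescence NAC gene, rose by 1.05 ± 0.07 and SAG13 by 1.07 ± 0.76, while SAG29 fell by 1.25 ± 0.08 and SEN1 by 1.05 ± 0.23. The SAG13 call ended without replicate 2 (1.11), and SAG13 was at 0.68 without replicate 1. Photosynthesis and chlorophyll genes had 19 of 33 higher and 2 lower (20 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.000671, adjusted p = 0.796 with an estimated correlation), while the root cell type markers had a median of -0.22 in the same comparison. LHCB6, a light-harvesting gene, rose by 0.75 ± 0.04 and PSBP1 by 0.68 ± 0.09, whereas LHCB1.3 fell by 0.97 ± 0.15 and RBCS2B by 0.70 ± 0.03. With fry the defence and senescence lists kept their calls (adjusted p = 0.0188 for each). The calls of all 3 lists ended with the authors' series table, those of defence and senescence also with median centring, and that of photosynthesis also with the scanner software's log ratio.

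Wall and root lists fell. Of 20 expansin and XTH genes 12 fell and 3 rose (13 and 3 adjusted over the list alone, median -0.37, camera adjusted p = 0.000853, adjusted p = 0.796 with an estimated correlation). XTH33 fell by 1.76 ± 0.28, XTH4 by 0.77 ± 0.21 and XTH17 by 0.76 ± 0.13, and EXPA5 rose by 0.76 ± 0.19. Of 21 secondary wall and lignin genes 9 fell and 0 rose, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.0168, adjusted p = 0.796 with an estimated correlation). The xylem protease gene XCP1 fell by 0.64 ± 0.09, and the lignin genes CAD4 and CCR1 fell by 0.47 ± 0.04 and 0.45 ± 0.07. Of 20 root cell type markers 10 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.00546, adjusted p = 0.796 with an estimated correlation). The endodermal genes CASP5 and CASP4 fell by 0.65 ± 0.15 and 0.35 ± 0.18, and the nitrate transporter gene NRT2.1 by 0.52 ± 0.03. PYK10, an abundant root glucosidase gene, was at 0.10 ± 0.05 and SCR at 0.02 ± 0.06, both chosen after their values were seen. The calls of the wall and lignin list and of the root markers also ended with median centring.

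Glucosinolate genes fell as a list, with 13 of 21 lower and 0 higher (15 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.000115, adjusted p = 0.796 with an estimated correlation). The chain elongation genes MAM1 and BCAT4 fell by 0.54 ± 0.06 and 0.48 ± 0.15, and SUR1 by 0.39 ± 0.11. Of 216 cytosolic ribosomal protein genes 65 fell and 13 rose (61 and 11 adjusted over the list alone, median -0.08, camera adjusted p = 0.000308, adjusted p = 0.796 with an estimated correlation), but with median centring the list was called higher (median 0.58, where the median gene lies at 0.46). RPL5B fell by 0.53 ± 0.07 and AT4G29410 by 0.51 ± 0.06. The glucosinolate call also ended with median centring and the ribosomal protein call with the authors' series table. Of 45 histone genes 14 rose and 2 fell, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.239; called higher with median centring), with HON4 at 0.44 ± 0.03 and HTB4 at 0.38 ± 0.05.

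The remaining lists were not called. Of 20 flavonoid and anthocyanin genes 5 rose and 2 fell, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.116), and without replicate 3 the flavonoid and anthocyanin genes were called higher (median 0.23, adjusted p = 0.00882 at the preset correlation; adjusted p = 0.796 with an estimated correlation over all 3 arrays). F3'H rose by 0.49 ± 0.14 and the regulator gene MYB111 fell by 0.49 ± 0.13. Of 19 circadian clock genes 4 rose and 7 fell (7 and 7 adjusted over the list alone, median 0.06, mean -0.01, camera adjusted p = 0.953), with CCA1 at 0.37 ± 0.05 and PRR5 at -0.47 ± 0.07. Of 12 flowering genes 1 rose and 3 fell (1 and 2 adjusted over the list alone, median 0.00, camera adjusted p = 0.793); SPL3 rose by 0.94 ± 0.12 and SEP3 fell by 0.67 ± 0.03. Of 10 trichome genes 1 rose and 2 fell, also when adjusted over the list alone (median 0.02, mean -0.01, camera adjusted p = 0.793), with GL1 at -0.18 ± 0.10, -0.15 without replicate 1 and -0.16 without replicate 2, where its call ended. Of 8 heat shock genes 0 rose and 2 fell, also when adjusted over the list alone (median -0.15, camera adjusted p = 0.0872; called lower without the filter on dim probes), with HSP18.2 at -0.48 ± 0.17. Among 13 reference genes often used for scaling, 5 rose and 3 fell (5 and 4 adjusted over the list alone, median 0.00, camera adjusted p = 0.634; called higher with median centring), with ACT8 at -0.60 ± 0.17 (n = 2) and UBQ10 at 0.36 ± 0.12.

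**Figure D4:**
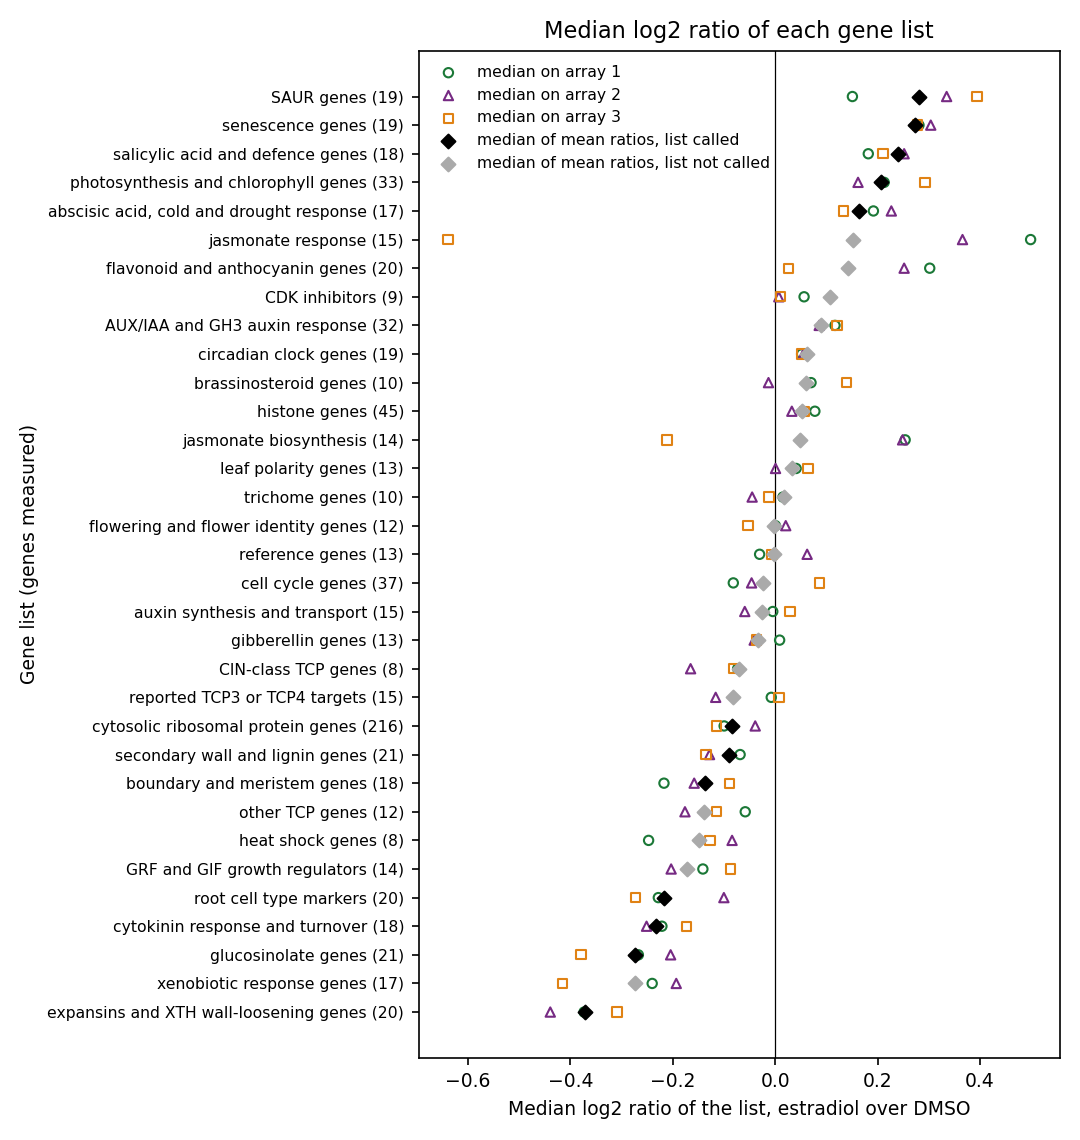
Median log2 ratio of estradiol over DMSO (x axis) for each of the 33 gene lists, with the number of genes measured in brackets. Open symbols are the medians on the 3 arrays and diamonds the median of the mean ratios, black where camera called the list at its preset correlation. The jasmonate response list lies at 0.50 and 0.37 on arrays 1 and 2 and at -0.64 on array 3.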

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

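The tests of exchanged RNA, of the DMSO plants alone, of the share of root tissue and of base composition were chosen after the results were seen. Probes without a locus name gave signal too, and were tested with the genes but take no part in the gene counts. Of 8812 probes named for a chromosome interval, 1069 were well above background in both channels on all 3 arrays, and among all interval probes tested 276 were called higher and 113 lower, with log2 ratios of the called probes from -0.96 to 0.74. Of 2430 probes with another name, 801 were well above background in both channels on all 3 arrays, and among all such probes tested 296 were called higher and 78 lower, with log2 ratios of the called probes from -0.94 to 1.51.

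Jasmonate genes had lower ratios on array 3 than on arrays 1 and 2, with a median difference of -0.79 over 29 spots. An exchange of both RNAs on array 3 is excluded by the TCP3 ratio of 3.59 there, and a local fault by the 705 neighbouring spots, whose median difference was -0.0084. A jasmonate state of the DMSO plants alone is argued against by the estradiol channel, which on array 3 lay below both other arrays in 15 of the 15 response genes, while the DMSO channel lay above both in 13. What differed between the plants of replicate 3 and the others stays open, and no biological explanation was tested.

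The 12 largest falls and the fall of the root markers could come from a lower share of root tissue in the estradiol RNA. As the whole cause of the largest falls this is excluded by the root markers' median of -0.217. Whether it was the only cause of the markers' own fall cannot be told from their spread. Their SD was 0.211, and they ran from -0.65 to 0.10. A changed share would itself give unequal falls if the markers are not equally specific to roots. A small change in the share of root tissue, beside changes in particular genes, stays open, also for the rise of the photosynthesis genes, and no biological explanation was tested.

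Small ratios were called in many genes. Base composition as the whole cause is argued against by the 8931 genes called after its correction, of which 8375 were called before it. A dye bias particular to each probe stays open for part of the genes: of 165 second probes that share no 15 bases with the first, 120 had its sign, which is 72.7% (exact 95% interval 65.3 to 79.4). A dye bias particular to each transcript cannot be told apart from the treatment, since 0 arrays had the opposite orientation. The real signs of the arrays gave 8922 genes and the highest of the other sign patterns 0 with limma. The other patterns had 26 to 181 genes at an unadjusted p under 0.05. Of the 4 patterns only the real one gave as many calls, and 4 are too few for a share under 0.05.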

How the results depend on the processing

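The centred series table, the correction for base composition and the test against 1.5-fold were chosen after the results were seen. TCP3 was called higher in every alternative in which its ratio was tested against 0, from 3.61 to 3.75 when leaving out 1 replicate. Counts of genes higher and lower stayed within 1.5 times of 4547 and 4375 in the alternatives, except with the series table (12038 and 1327), with median centring (15709 and 1710), when tested against 1.5-fold (54 and 140), and without replicate 1 or 2 (leaving out each replicate gave 2480 to 4694 higher and 2531 to 4506 lower). The series table carries a constant and puts the median gene at 0.26; centred on its medians it gave 3174 and 3903. Median centring sets the median of all spots with weight to 0, dim ones included, and puts the median gene tested at 0.46. With loess, which removes a trend of the ratio with intensity, that median lies at 0.0062. The shift thus follows intensity, and the cause of this trend was not tested. Leaving out any replicate leaves fewer arrays, yet without replicate 3 the counts were 4694 and 4506. The number of arrays alone thus does not account for the lower counts without replicate 1 or 2, where array 3 was kept. Arrays 1 and 2 correlated at 0.9, against 0.753 and 0.77 for their pairs with array 3. A test against 1.5-fold asks for larger changes. The number of gene lists called was 12, against 0 with an estimated correlation, 2 with fry, 7 with median centring and 13 to 17 without 1 replicate. The senescence and defence lists lost their calls too, though their estimated correlations (-0.0343 and -0.0437) lay below the preset 0.01. For these 2 lists a correlation above the preset was thus not why the calls ended. At an estimated correlation camera uses the residual degrees of freedom of only 3 arrays, and at a preset one it does not. That form had little power here, and all 12 called lists shared an adjusted p of 0.796 with it. Over these 12 lists the estimated correlations ran from -0.0437 to 0.394, so the preset of 0.01 is low for some. Of 2538 values of named genes under the alternatives, 2308 kept their side of the threshold without a reversal of a called value, 177 lost the call, 8 gained it and 45 reversed; of 594 list values these were 540, 37, 16 and 1. Among the values that kept their side, 9 gene values and 20 list values changed sign with no call in either setting. Uncalled lists that gained a call numbered 3 without the filter on dim probes and 2 with the series table. There was 1 such list with no background correction and 1 with an offset of 10. In the series table the log2 ratios that reversed were TCP13 0.24, TCP24 0.0899, KRP1 0.0026, TCP14 0.026, REV 0.083, KRP5 0.0905 and HSP70-4 0.061. With median centring they included TCP2 0.41, TCP5 0.27, TCP10 0.15, TCP13 0.50, TCP24 0.41, KRP1 0.26, SAUR16 0.42, GIS 0.34, TCP21 0.11, TCP14 0.38, TCP6 -0.11 (dim with DMSO on all arrays, so its sign is not settled), LSH3 0.0401, AS2 0.13, REV 0.37, CYCD3;2 0.016, CDKB1;1 0.22, KRP5 0.23, AOC3 0.10, JAZ6 0.13, TAA1 0.16, GL1 0.15, RBCS2B 0.20, ARR4 0.17, GA2OX6 0.026, HSP70-4 0.41, CCR2 0.14, ACT8 0.11, CYP86A1 0.18, CAD4 0.19, CCR1 0.22, MAM1 0.15, BCAT4 0.15, SUR1 0.26, CYP79F1 0.23, AT4G29410 0.18, AT5G02450 0.16 and AT3G25520 0.31, and the median of the cytosolic ribosomal protein genes was 0.581. Relative to the median gene, 7 of the 7 and 36 of the 38 genes kept their sign, and TCP13 did not; TCP6 cannot be read this way. The cause was not tested. A fit with slide as a block could not be made with all arrays on 1 slide, leaving out saturated spots changes nothing since there were 0, and the search for TCP binding sites was not run without a genome sequence. Signal over background limits the genes that were dim in 1 channel, of which 85 were called.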

Other observations

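The gene groups and the test here were chosen after the results were seen. Genes of the iron deficiency response moved in both directions. Of 20 measured, 10 were higher and 3 lower. Beside bHLH38, bHLH39 and bHLH100, the related gene bHLH101 rose by 1.37 ± 0.84 (SD, n = 3), the peptide genes IMA1 and IMA2 by 0.95 ± 0.79 and 1.44 ± 0.88, the transporter gene ZIF1 by 0.91 ± 0.32, the iron transporter gene IRT1 by 0.67 ± 0.35 and BTS by 0.61 ± 0.24. Without replicate 1, IMA1 was at 0.54 and bHLH101 at 0.89, and without replicate 2 the IMA1 call ended (0.98). FIT, for a regulator of iron uptake, fell by 0.55 ± 0.12, NAS4 by 0.53 ± 0.18 and the coumarin synthesis gene F6'H1 by 0.88 ± 0.27.

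Of 8 measured genes of the thalianol and marneral triterpene clusters, 8 were lower. THAS1, the thalianol synthase gene, was 2.47-fold lower (SD of the log2 ratio 0.40, n = 3) and was well above background with estradiol on 2 of the 3 arrays, and CYP708A2 fell by 1.96 ± 0.26, AT5G47950 by 1.34 ± 0.11 and CYP705A12 by 0.73 ± 0.19, beside CYP705A5, AT5G47980 and CYP71A16. MRN1, the marneral synthase gene, was not well above background with estradiol on any array and was at least 1.36-fold lower.

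Neighbouring genes may change together among the 137 genes lower by at least 2-fold. They held 10 adjacent pairs of tested genes whose probes share no 15 bases, against a median of 1 and at most 6 in 10000 random sets of as many genes, and the 70 genes higher by at least 2-fold held 2 pairs, against a median of 0, a 95th percentile of 1 and at most 4. Pairs of the lower genes included AT4G12545 and AIR1, MLP328 and MLP329, and FRO6 and FRO7, and several pairs are related genes. Others form 1 chain of the thalianol cluster, from AT5G47980 through CYP705A5 and CYP708A2 to THAS1. Random sets of single genes do not allow for such clusters or related neighbours. Binding of a related transcript through shorter shared sequence stays open.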
